A study of Danio rerio with 6 samples.

How the data were processed

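Single-cell RNA sequencing was done on adult zebrafish aged 6 months that carry a transgene in which the mpeg1.1 promoter drives the red fluorescent protein DsRedx in macrophages and related cells. There was 1 library each for brain, heart, liver, gill, epidermis and intestine. Per the labels' protocols, each library was made from the pooled organs of 6 fish of both sexes, DsRedx-positive and DAPI-negative cells were sorted, 30000 cells were collected per organ, and the 10x Genomics 3' v3.1 kit was sequenced on a NovaSeq 6000 to a target of about 100000 read pairs per cell.

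The deposited matrices hold unfiltered UMI counts per gene and barcode, made by Cell Ranger 4 per the file headers. The submitters' processing notes name Cell Ranger, Seurat 4.0.5 and the GRCz11 (danRer11) genome. The 6 matrices list between 1120753 and 1976136 barcodes each and share 25108 genes, DsRedx included. The liver and heart matrices list EGFP as 1 more row, which stayed out of all tests. Gene symbols were used as the files pair them with Ensembl gene IDs. No cell annotation by the authors was used.

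A barcode was called a cell with at least 1000 UMIs, at least 500 detected genes and at most 10% of its UMIs from mitochondrial genes. Doublets were called in each library with Scrublet as run by scanpy, with an expected rate of 0.8% per 1000 cells. Its automatic threshold marked 1.55% of the heart barcodes and between 0.0977% and 0.208% in the other 5 libraries, where the caller is taken not to have worked, so doublets remain in those libraries. Removal of the highest scores at the expected rate was added as an alternative after seeing the data. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave 33 clusters. Libraries were not integrated.

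Clusters were named from 16 marker lists fixed before the data were examined. The scoring rule was chosen after seeing the clusters. A marker counted as raised when its CPM was at least 2-fold that of the median cluster, after adding 10 CPM to both, and it was detected in at least 10% of the cluster's cells. A name needed at least 5 raised markers or at least 50% of its list, with a minimum of 3, and the highest mean log2 excess. A cluster stayed unnamed when another list with at least 4 raised markers reached 50% of that excess. The top 10 genes of each cluster by fold were then compared with the markers. The fold was taken against cells outside the cluster's class, in the same libraries and in all libraries. Other clusters of the same class were thus left out, and an unnamed cluster was set against all other cells. Within libraries no macrophage-like or DC-like cluster led with markers of another class. Against all libraries, clusters 0, 6, 18 and 30 each had 1 marker of another class and 0 of their own among these genes, namely cd8a in cluster 0 and rbp2a in clusters 6, 18 and 30. Macrophage-like cells are therefore given with their cluster numbers, and metaphocyte-like cells, whose clusters lead with grn2, are compared by cluster. Exceptions are the class shares drawn per organ and the share of metaphocyte-like cells with cd8a.

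Shares of cells carry exact (Clopper-Pearson) 95% intervals, summed UMIs carry exact Poisson 95% intervals, and both cover counting error only. With 1 library per organ no test between organs is possible, and no p-value, standard error or number of changed genes is given for them. Levels are CPM, counts scaled to a fixed total, of the summed UMIs of a class in a library, given where the class held at least 50 cells, or at least 20 where immediate early genes are compared in other classes. A ratio is set against the highest of the other organs, with libraries under 3 counts set at 3 counts for that library.

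The only tested comparison set macrophage-like against DC-like cells. UMIs were summed per class and organ, with at least 30 cells per sum, and the 12 sums of 6 libraries were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, its default expression filter, organ as a block, Benjamini-Hochberg adjustment). The block follows the design, since both sums of an organ come from the same fish and the same library. The p-values measure how far the difference between classes repeats over 6 organs, not over fish. The 16 marker lists and 15 gene lists, all fixed before the data were examined, together hold 339 genes. Of these, 323 matched by symbol, 3 by gene ID and 13 did not match. The 15 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated. Across organs, a list is described by the median log2 ratio of its members to the mean log2 level of the other organs, with a pseudocount of 1 CPM, over members with at least 10 CPM in at least 1 organ, and by the percentile of that median among 10000 random lists matched on mean expression in 20 bins. In each direction of the tested comparison, the 12 genes named have an adjusted p under 0.05, the same direction in every organ, at least 50 CPM on average in the higher class and the largest log2 fold changes. For each organ, the 5 genes named in macrophage-like and the 3 in DC-like cells have the highest ratio to the highest other organ, with at least 50 CPM and at least 30 counts. Both rules pass over markers, mitochondrial and ribosomal genes and clone-style names. The rule across organs also passes over genes at least as high in the ambient profile as in the class.

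Ambient RNA was profiled from barcodes with 10 to 99 UMIs. Its share of a class's UMIs was estimated from the 3 parenchymal markers with the lowest ratio and at least 50 ambient UMIs, and the lower of the macrophage-like and DC-like estimates was taken: 1.77% in the epidermis, 1.78% in the gill, 7.33% in the intestine, 22.7% in the liver and, from 1 marker, 4.70% in the brain. No heart marker allowed an estimate. The intestine had only the markers tm4sf4 and rbp2a. Since rbp2a is itself high in intestinal macrophage-like cells, their estimate was 226% and the DC-like one was taken, so the intestinal share is uncertain. The low-UMI barcodes of each library include cells of 1 other library, in the pairs epidermis and gill, intestine and brain, and liver and heart, so a profile without such barcodes was added as an alternative after seeing the data.

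The test was run on simulated counts for 11799 genes with 200 changed ones. It recovered 57% of genes changed 2-fold and 95% of those changed 4-fold, with 3 false calls. Every simulated gene had the same dispersion, and organ effects were shared by both classes. Real genes vary in both respects, so these rates need not hold for the real counts. In simulated libraries for the list statistic over 6368 genes, a 2-fold change of the lysosomal list in liver gave a median log2 ratio of 0.97 and percentile 100. Alternatives planned before the data were examined covered the UMI minimum (500 with at least 250 genes, or 2000), the mitochondrial limit, doublets kept, the clustering resolution, centring each gene within its library, the expression filter, the scaling, the organ block, each organ left out, DESeq2 1.42.0, classes built on a random part of each cell's UMIs and tested on the other part, ambient subtraction and thinning of each cell to 1000 UMIs. Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6 and scipy 1.17.1, and R 4.3.3, were used.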

Results

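Macrophages and dendritic cells reside in most organs, and the series profiled mpeg1.1-driven DsRedx-positive cells of 6 zebrafish organs to compare these populations between tissues. The 6 groups were epidermis, gill, intestine, liver, heart and brain, each with 1 library from a pool of 6 fish. Over the shared genes, without the EGFP row, the matrices held 48315471 UMIs in total for the epidermis, 63014751 for the gill, 52215441 for the intestine, 47533753 for the liver, 63925521 for the heart and 30806950 for the brain. Of the 30000 cells sorted per organ, 3362 epidermal, 6136 gill, 3860 intestinal, 4747 liver, 4823 heart and 3483 brain barcodes were called as cells, with median depths of 9322, 3212, 6052, 4840, 6879 and 4924 UMIs. There were no replicate libraries of any organ, and differences between organs have no replicate check.

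The first question was which cells the sorted libraries hold in each organ. Macrophage-like cells made up most of the called cells in the liver and brain, while macrophage-like and DC-like cells were about equally frequent in the heart. B cell-like cells were the largest named class of the gill, and metaphocyte-like clusters lay almost wholly in the epidermis and gill. The macrophage-like share was 83.8% (95% exact interval 82.7–84.9%) in the liver, 68.8% (2395 of 3483 cells) in the brain, 45.5% (44.0–47.1%) in the intestine, 39.3% (37.6–41.0%) in the epidermis, 39.0% (37.6–40.4%) in the heart and 7.32% (6.678–7.998%) in the gill, a range of 76.5 percentage points. The DC-like share was 40.9% (39.5–42.3%) in the heart, 23.8% (22.5–25.2%) in the intestine, 20.9% (19.6–22.3%) in the brain, 13.2% (12.1–14.4%) in the epidermis, 12.9% (12.03–13.72%) in the gill and 2.001% (1.62–2.44%) in the liver, a range of 38.9 percentage points. B cell-like cells made up 29.6% (28.5–30.8%) of gill cells and between 0.590% and 6.19% elsewhere. T, NK or ILC-like cells made up 12.4% of heart and 7.58% of liver cells and at most 1.27% elsewhere. Enterocyte-like cells were 3.21% of intestinal cells, and hepatocyte-like cells were 1.79% of liver cells. No cluster met the naming rule for the other marker lists: neutrophil, thrombocyte, erythroid, keratinocyte, ionocyte, cardiomyocyte, neuron or glia, endothelial and fibroblast. Some came close but raised the markers of another list too. Unnamed cluster 1 (351 epidermal cells, 10.4%), which leads with icn2, krt97, krt91 and krt5, and cluster 13 (637 gill cells) each had 8 raised keratinocyte markers, beside 5 and 4 metaphocyte markers. Cluster 17 (85 cells, 59 of them from the heart) had 6 endothelial and 6 fibroblast markers. Unnamed clusters held 31.05% of gill, 19.95% of intestinal and 16.45% of epidermal cells but 8.47% of brain and 4.02% of liver and heart cells. The sort gate, the tissue dissociation and the UMI minimum can set these shares. A share also does not show that the reporter marks a class. In the heart, DsRedx had 299 UMIs over 599 T, NK or ILC-like cells and 132 over 177 B cell-like cells. The 1972 DC-like cells of that library held 8414. In the liver, 85 hepatocyte-like cells held 83. The main macrophage-like cluster of the brain, 26, rested on 5 raised markers and stayed unnamed with a minimum of 500 UMIs and 250 genes, where the brain share was 0.951%.

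**Figure D1:**
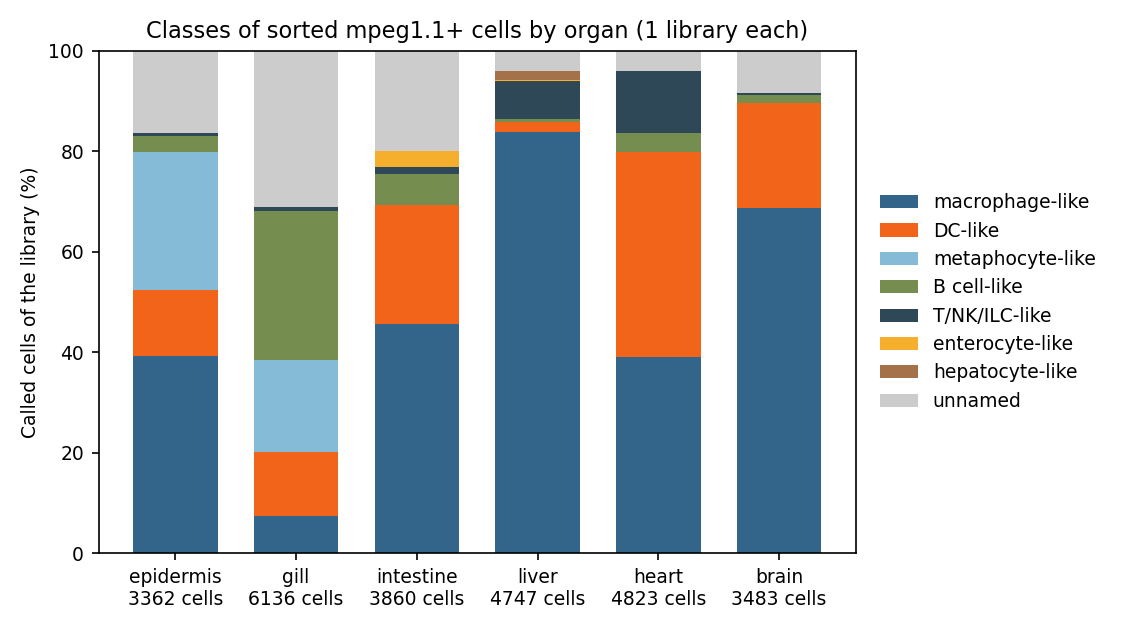
Stacked bars give each class as a percentage of the called cells of 1 library per organ. The macrophage-like share runs from 7.32% in the gill to 83.8% in the liver, and the DC-like share from 2.001% in the liver to 40.9% in the heart.

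Metaphocytes are ectoderm-derived cells that resemble macrophages, and here their clusters are compared by number. The genes grn2, epcam and cldnh were high in all 3 clusters, while spi1b and ptprc were low. Cluster 2 held 23.8% (22.3–25.2%) of epidermal cells, cluster 10 held 14.2% (13.4–15.1%) of gill and 3.06% of epidermal cells, and cluster 11 held 3.88% of gill cells. The gene grn2 stood at 65390 CPM in cluster 2, 120600 CPM in cluster 10 and 210500 CPM in cluster 11, epcam at 3014, 1979 and 1759 CPM, and cldnh at 3484, 5071 and 6944 CPM. The leukocyte gene ptprc reached between 8.97 and 17.1 CPM in these clusters. Of the paired PU.1 genes, spi1a stood at 818 CPM in cluster 2, 830 CPM in cluster 10 and 550 CPM in cluster 11, and spi1b at 10.6, 19.2 and 17.0 CPM. In macrophage-like cells both genes were present, spi1b at 1023 and spi1a at 453 CPM in the epidermis. In these clusters the intestine and liver had 0 cells, for which the exact intervals reach up to 0.0955% and 0.0777%.

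Which genes separate macrophages from dendritic cells in every organ was asked with macrophage-like against DC-like sums of the same libraries. Macrophage-like cells carried the growth factor gene igf2b, the metalloproteinase gene mmp14b and the metalloproteinase inhibitor gene timp2b. DC-like cells carried syngr3b, spock3, the chemokine ccl35.2 and the transcription factor gene znf366. With edgeR's quasi-likelihood test, 1189 of 10974 genes were higher in macrophage-like cells and 914 in DC-like cells at a Benjamini-Hochberg adjusted p under 0.05, of which 956 and 744 went the same way in all 6 organs. The count of genes higher in DC-like cells was 609 without the gill and 543 without the intestine. The following genes went the same way in 6 of 6 organs. igf2b averaged 160 ± 81.5 CPM in macrophage-like and 4.25 ± 3.73 CPM in DC-like cells (SD, n = 6 libraries), a log2 fold change of 5.55 ± 0.28 (SE; edgeR adjusted p 1.5e-05). robo4 (log2 fold change 5.38 ± 0.37), mmp14b (5.03 ± 0.43), rgl1 (4.97 ± 0.22), cd4-1 (4.86 ± 0.44) and zeb2a (4.82 ± 0.30) followed with adjusted p between 1.5e-05 and 0.00015. fabp7b (5.25 ± 0.26), timp4.3 (5.03 ± 0.26), ccl34b.8 (5.00 ± 0.30), timp2b (4.84 ± 0.43) and lgals3bpb (4.84 ± 0.43) lay in the same range. Some of these genes were near absent in single organs: in the brain cd4-1 had 1 UMI in macrophage-like cells (0.0673 CPM) and 0 in DC-like cells, and fabp7b stood at 0.943 CPM in brain and 4.95 CPM in heart macrophage-like cells. On the DC-like side, nrp2a stood at 0.233 CPM in the intestine. The gene tppp stood at 14660.7 CPM in gill and 8612 CPM in intestinal macrophage-like cells against 13.4 CPM in the heart and 17.4 CPM in the brain. Among the DC-like genes, syngr3b averaged 3.71 ± 2.05 CPM in macrophage-like and 622 ± 166 CPM in DC-like cells, a log2 fold change of −7.50 ± 0.42 (edgeR adjusted p 2e-05). ccl35.2 averaged 16.0 ± 14.3 and 1759 ± 1234 CPM. spock3 (−7.05 ± 0.43), nrp2a (−6.95 ± 0.31), msi1 (−6.77 ± 0.24), ackr3b (−6.17 ± 0.40) and sult5a1 (−6.13 ± 0.30) had adjusted p of at most 3.3e-05. afap1l2, prox1a, nrxn1a, znf366 and actn1 had log2 fold changes between −6.04 and −5.58. Most of the genes named here are also among the 10 leading genes of clusters, against the same library or all libraries. Only robo4, mmp14b, rgl1, cd4-1, zeb2a, nrp2a, prox1a, nrxn1a and znf366 are not.

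**Figure D2:**
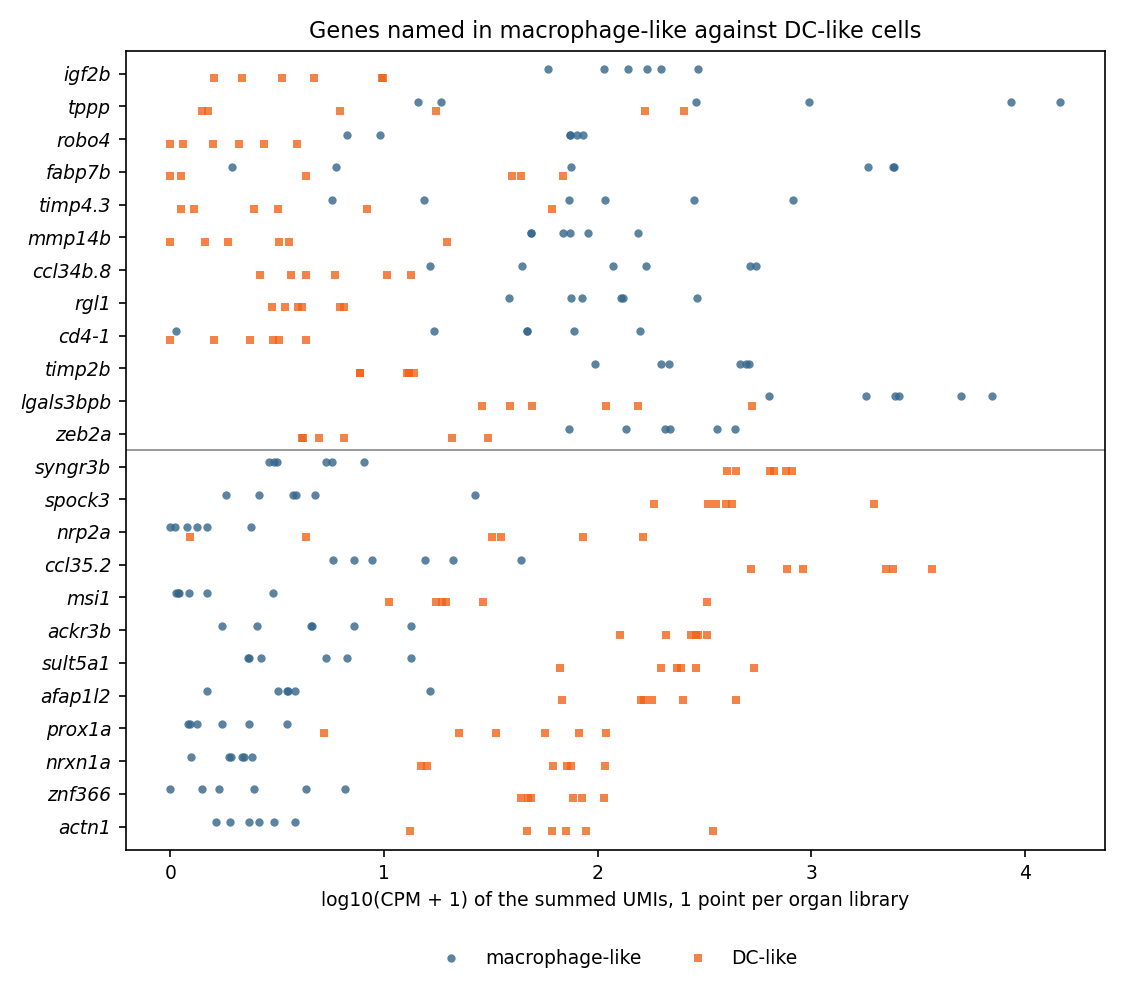
Each point is the level of a gene in the summed UMIs of 1 class in 1 organ library, on a log10(CPM + 1) axis, with macrophage-like and DC-like cells in separate colours. The 12 upper genes lie higher in macrophage-like and the 12 lower genes higher in DC-like cells in each of the 6 organs.

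Among the gene lists fixed in advance, macrophage-like cells were higher for microglia-associated and scavenger receptor genes at both correlations, and for complement and lysosomal genes by the preset test alone. Antigen presentation, interferon and immediate early genes did not separate the classes as lists. The microglia-associated list was higher in 8 of 9 genes (9 adjusted over the list alone), with a median log2 fold change of 3.87 and camera adjusted p of 1.9e-12 at the preset and 0.0054 at the estimated correlation. Its members included lgals3bpb (4.84), ccl34b.1 (4.74), p2ry13 (4.50), p2ry12 (3.81) and apoeb (3.63), and hexb missed the threshold (adjusted p 0.077). All 7 scavenger and efferocytosis genes were higher, mrc1b by 4.79, stab1 by 4.74 and timd4 by 3.35, with adjusted p of 2.7e-16 and 0.0054, and 2 of the 7 are macrophage markers. The complement list was higher in 3 of 4 genes, all 3 of them c1q markers, with adjusted p of 2.1e-08 that became 0.103 with the estimated correlation. The lysosomal list was higher in 12 of 19 genes (14 adjusted over the list alone), including gpnmb (5.01), ctsd (3.11) and ctsz (2.58), with adjusted p of 1.7e-06 that became 0.157. psap (0.02) and npc2 (−0.23) did not differ detectably. A separate entry, NPC2, is not among the tested members of this list. It was a leading gene of macrophage-like clusters 6, 18 and 20, at 1051, 2273 and 435 CPM. Cells of the same libraries outside the macrophage-like class stood at 67.5, 67.5 and 61.1 CPM. Proliferation genes were higher in DC-like cells for 3 of 12 genes (6 adjusted over the list alone), stmn1a (−2.34), birc5a (−1.21) and hmgb2a (−0.94), and the adjusted p of 0.040 became 0.157. The 508 cycling cells of unnamed cluster 3 are in neither class, so this list does not compare how many cells cycle. Inflammatory cytokines split, with cxcl19 (3.09), cxcl8a (2.78) and cxcl8b.1 (2.77) higher in macrophage-like cells and il12bb (−4.92), tnfa (−2.84), ptgs2b (−2.18), tnfb (−1.28) and il1fma (−0.65) higher in DC-like cells (list adjusted p 0.541). MHC class II presentation also split, with ctss2.1 (1.71) against cd83 (−1.29) and cd40 (−1.03), while cd74a did not differ detectably (−0.41, adjusted p 0.54; list adjusted p 0.442). Of the myeloid transcription factors, 5 of them class markers, cebpa (4.47) and klf4 (2.82) stood on the macrophage-like side and irf4a (−7.25) and nr4a3 (−2.07) on the DC-like side (list adjusted p 0.442). Of the remaining lists none passed the preset test: lipid handling (adjusted p 0.1996; apoc1 3.90, fabp11a 2.11), heme and iron (0.343; slc40a1 2.67, hmox1a 1.18), MHC class I (0.757), interferon response (0.697; stat1b −2.19), actin and migration (0.757; itgae.1 3.65, arpc1b −1.31), immediate early and heat shock (0.948) and chemokine receptors (0.948; ccr2 2.98, cxcr3.3 2.32, xcr1a.1 −3.22). For chemokine receptors the list median of −0.16 and mean of 0.37 differ in sign. MHC class I medians of macrophage-like over DC-like cells differed in sign between organs, which was not tested. They were 0.73 in the epidermis, 0.46 in the gill and 0.41 in the intestine. In the liver, heart and brain they were −0.95, −0.93 and −0.69.

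How tissue residence marks macrophages was asked by comparing macrophage-like cells between organs. Brain macrophage-like cells stood furthest apart, with apolipoprotein genes far above any other organ. Epidermal cells led with pleca and anxa2a, intestinal cells with the protease gene ctss1 and gill cells with GGH. The leading ratios of gill and heart cells were smaller, and so were those of liver cells apart from vtg1. The cells lay in clusters 0 and 4 (epidermis), 16 (gill), 6 and 18 (intestine), 28, 20 and 30 (liver), 15 (heart) and 26 (brain), so organ, library and cluster coincide. In the brain, apoc1 stood at 46220 CPM and apoeb at 7619 CPM, 218 (counting interval 212–225) and 331 (303–363) times the liver, the highest other organ. Both genes, and g0s2 at 1429 CPM, are among the leading genes of brain cluster 26, and g0s2 was 1089 (671–1906) times the epidermal level. tgm2l stood at 231.5 CPM in the brain and was at least 336-fold higher than in any other organ, and dok4 stood at 81.8 CPM against 0.230 CPM in the gill, where 1 UMI was counted. Ambient levels in the same library came close to those of the cells for g0s2 (1256 CPM) in the brain, anxa2a (806 CPM) in the epidermis and cox6a2 (306 CPM) in the intestine. In the epidermis, pleca stood at 1566 CPM (1544–1589), 21.0 times the gill, followed by anxa2a (953 CPM, 10.6-fold), snap91a (78.0 CPM, 7.54-fold), sox9b (228.0 CPM, 6.53-fold) and syne1b (203 CPM, 5.78-fold). In the gill, GGH (ENSDARG00000105118) stood at 792 CPM, 8.12 times the epidermis, and slc6a9, sash1a, mxc and gig2h were between 2.27 and 5.09 times the highest other organ. The interferon response list as a whole was nevertheless low in the gill. In the intestine, ctss1 stood at 58.0 CPM, 58.9 (33.6–114) times the epidermis, and epdl1 at 2017 CPM, 4.48 times the epidermis, with dlc, cox6a2 and saa between 4.19 and 7.66. In the liver, kazald3 (6.03-fold), sox11b (3.80), a cxcl11.6 copy (ENSDARG00000094706; 3.68) and tlr3 (3.45) came after vtg1. The yolk protein gene vtg1 was counted in the liver alone, at 89.1 CPM and at least 129-fold higher, but its ambient level in that library was 78.0 CPM, or 93.8 CPM without barcodes shared with another library. In the heart, cdaa (4.09-fold), gpc1b (3.92), tagln2 (3.71), ecm1b (3.60) and ccl39.1 (3.33) led, with tagln2 at 1107 CPM.

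**Figure D3:**
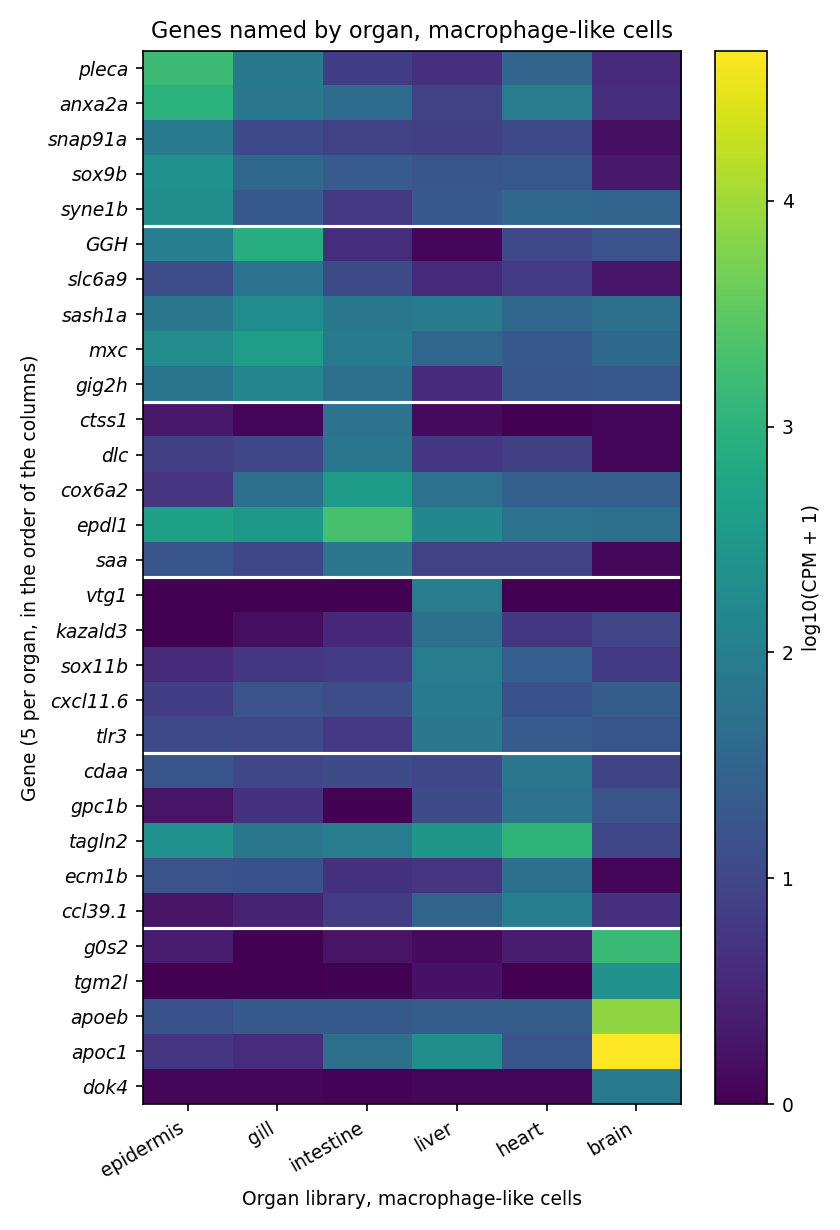
Colour gives the level, as log10(CPM + 1), of each named gene in macrophage-like cells of the 6 organs, 1 library each. The 5 brain genes stand between 81.8 and 46220 CPM in the brain and no higher than 212 CPM in the other organs.

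Across the fixed lists, brain macrophage-like cells were high for microglia-associated, lipid handling, immediate early and myeloid transcription factor genes and low for C1q, MHC class II and iron genes. Liver cells were high for interferon response and immediate early genes. Epidermal and gill cells were high for both MHC lists and inflammatory cytokines, and intestinal and epidermal cells for lysosomal genes. The medians are log2 ratios to the other organs, with the percentile among random lists, for 15 lists in 6 organs. The microglia-associated median was 1.77 (percentile 100) in the brain and between −1.15 and −0.92 in the epidermis, gill and heart, and ccl34b.1 stood at 12640 CPM in the brain against at most 1345 CPM elsewhere. Lipid handling stood at 1.82 in the brain (percentile 100) and −1.42 in the gill (0), with fabp11a at 1036 CPM in the brain, 764 CPM in the intestine and 3.68 CPM in the gill. Of its 8 members 5 were higher in the brain. The list shares apoeb and apoc1 with the microglia-associated list, so the brain medians of these lists are not independent. The complement list, left with c1qa, c1qb, c1qc and cfd and no C3 gene, stood at −2.71 in the brain (percentile 0.14). There c1qb was at 475 CPM against at least 2325 CPM elsewhere. Immediate early and heat shock genes stood at 1.87 in the brain and 1.24 in the liver (both percentile 100), with fosab at 8184 and 8507 CPM, and at −1.34 in the epidermis (0). Interferon response genes stood at 1.87 in the liver (percentile 100) and 1.08 in the epidermis (99.97), with isg15 at 419.5 and 472 CPM, rsad2 at 60.7 and 51.6 CPM, against −0.90 in the gill (0), where isg15 was at 15.2 CPM. The brain median for this list was lower still, at −1.145 (percentile 0.05). Lysosomal genes stood at 0.78 in the intestine (percentile 100) and −0.58 in the heart (0), and lgmn was at 4936 CPM in the intestine and 897 CPM in the heart. MHC class II genes stood at 0.71 in the epidermis and −1.01 in the brain (percentile 0.125), and MHC class I at 0.93 in the gill (100) and −0.64 in the heart (0.15), with b2m at 6992 and 1768 CPM. Inflammatory cytokines stood at 0.99 in the gill and −0.88 in the heart (0.02), and cxcl19 at 8525 CPM in the intestine and 29.2 CPM in the brain. Scavenger receptors stood at 0.69 in the liver (98.9), where slc40a1 of the heme and iron list was at 956 CPM against 292 CPM in the heart and at most 63.1 CPM elsewhere. The heme and iron median itself was lowest in the brain (−0.83, percentile 0.765), and myeloid transcription factors stood at 0.85 there (99.8), although runx3 was at 0.269 CPM in the brain and 520 CPM in the epidermis. Proliferation, chemokine receptor and actin and migration lists lay within the central 95% of random lists in every organ, and for proliferation the cycling cells of cluster 3 are left out.

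**Figure D4:**
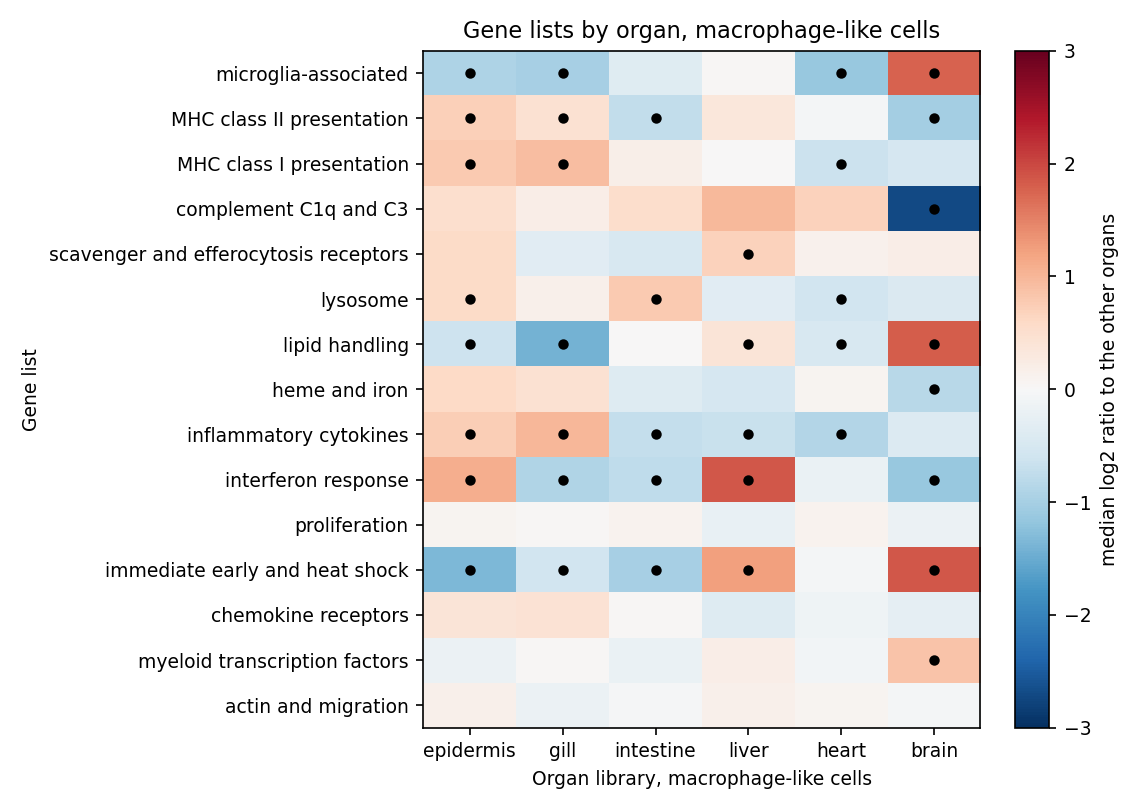
Colour gives the median log2 ratio of each gene list in macrophage-like cells of 1 organ library against the mean of the other organs. Black dots mark medians by their percentile among random lists. The interferon response list stands at 1.87 in the liver, and the microglia-associated list at 1.77 in the brain.

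DC-like cells were compared between organs in the same way. Liver DC-like cells were highest for the interferon response list, gill cells led with p2rx1 and brain cells with cnn3a and arhgap12b. The epidermis and gill shared high levels of inflammatory cytokines and MHC class II genes, and the heart was low for both. The cells lay mostly in cluster 7 (epidermis and gill), 22 and 25 (intestine), 24 (heart) and 27 (brain). Of the 95 liver cells, 75 lay in clusters 22 and 25, 14 in cluster 24 and 6 in cluster 7. In the liver, from 95 cells, ifit8 stood at 127 CPM and mxb at 99.1 CPM, at least 104-fold and 81.5-fold higher than in any other organ, and lgals17 was 9.42-fold higher. In the gill, p2rx1 stood at 112 CPM, at least 34.04-fold higher, and ccl39.5 and ccl39.2 were 12.3-fold and 9.36-fold higher. In the brain, cnn3a stood at 894 CPM, at least 271-fold higher, arhgap12b at 939 CPM, 150-fold, and iqsec1b at 295 CPM, at least 89.5-fold higher. In the intestine, ckba was 17.7-fold, kif9 7.18-fold and ccn1 6.93-fold higher, and in the epidermis mtbl 11.0-fold, myh11a 6.77-fold and slc7a11 5.97-fold. In the heart, lrrc15 was 8.79-fold, gpx1b 8.62-fold and itga4 7.19-fold higher. The interferon response median was 2.04 in the liver (percentile 100) and −1.15 in the intestine (0), and isg15 stood at 470 CPM in the liver and 3.38 CPM in the intestine. Inflammatory cytokines stood at 1.42 in the gill and 1.28 in the epidermis (both percentile 100) and −2.05 in the heart (0), with il12bb at 1508 CPM in the epidermis and 30.4 CPM in the heart and tnfb at 5167 CPM in the gill and 483 CPM in the heart. MHC class II genes stood at 1.04 in the epidermis, 0.78 in the gill and −0.95 in the heart (percentile 0.23), and cd74a at 61320 CPM in the epidermis and 16930 CPM in the heart. Brain medians were also negative, at −0.59 for MHC class II (percentile 22.34) and −0.89 for inflammatory cytokines (3.05). Immediate early and heat shock genes stood at 1.37 in the gill (percentile 100), where jun was at 5553 CPM. Liver DC-like cells were highest for the complement (2.16), scavenger receptor (1.43) and lipid handling (0.82) lists, in a library whose ambient share was estimated at 22.7%. Myeloid transcription factors stood at 1.16 in the brain and −0.91 in the epidermis. Heme and iron genes stood at 0.65 in the gill and −0.88 in the brain, chemokine receptors at 0.62 in the gill and −0.99 in the heart, lysosomal genes at −0.92 in the heart, and actin and migration genes at −0.44 in the gill. The microglia-associated median was 2.93 in brain DC-like cells, where apoc1 stood at 3019 CPM. Ambient apoc1 was at 31610 CPM in that library, and the ambient share was estimated at 4.70% from 1 marker. TMM scaling shifted the log2 levels of all genes of DC-like cells by 0.44 in the heart, −0.54 in the brain, −0.26 in the liver and 0.18 in the epidermis, and of macrophage-like cells by −0.19 in the gill, and the directions of the medians given here held under it.

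Whole profiles were compared by Spearman correlation across genes, which are not independent replicates. Over the 15 pairs of organs the median was 0.763 in both macrophage-like cells (6023 genes) and DC-like cells (6002 genes). Macrophage-like cells were closest between epidermis and gill (0.901), liver and heart (0.891) and gill and intestine (0.881), and furthest between epidermis and brain (0.667). DC-like cells were closest between epidermis and gill (0.924), gill and intestine (0.857) and intestine and liver (0.848) and furthest between liver and brain (0.577). Macrophage-like and DC-like cells of 1 organ correlated at between 0.723 in the brain and 0.778 in the heart. The libraries also fall into pairs by shared barcodes, epidermis with gill, liver with heart and intestine with brain, and this pairing matched 2 of the 3 closest macrophage-like pairs, while intestine and brain correlated at 0.683. Among the closest DC-like pairs it matched only epidermis and gill. In DC-like cells liver and heart correlated at 0.806 and intestine and brain at 0.600.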

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

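The tests of this part were set before their results were seen, although the pattern they address was noticed in the data. The liver and heart matrices carry counts for EGFP, a gene that is in no comparison of the report and that the labels do not mention. The liver library held 1864 EGFP UMIs, 1145 of them in called cells, and the heart library 1872, of which 1365 were in called cells. In called cells EGFP amounted to 14.7% of the DsRedx UMIs in the liver and 11.3% in the heart. DC-like cells stood at 65.5 CPM of EGFP and macrophage-like cells at 13.6 CPM in the heart, but at 56.2 (41.8–73.8) and 47.5 (44.5–50.5) CPM in the liver. The other 4 matrices list no EGFP row, so its level there is unknown.

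Immediate early and heat shock genes differed between macrophage-like and DC-like cells in opposite directions, most strongly in 2 organs. The list's median log2 ratio of macrophage-like to DC-like cells was 1.48 in the liver, with fosab and egr1 among the higher genes, and −1.48 in the gill. It was 0.76 in the brain, 0.57 in the heart, −0.81 in the epidermis and −0.12 in the intestine. The difference between the organs was not tested, since each organ has 1 library.

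The same genes stood high in brain and liver macrophage-like cells against the other organs, with medians of 1.87 and 1.24. Tissue dissociation can induce fosab, egr1 and hsp70.3 in every cell, so B cell-like cells of the same libraries were compared. In the liver the B cell-like median was −0.76 over 28 cells, past the bound set in advance. This goes against handling that acted on every liver cell but does not settle it. The cells are few, and the B cell-like clusters also differ between organs. Cluster 8 held 89.3% of the liver B cell-like cells and 53.3% of those of the gill. The T, NK or ILC-like (0.11) and DC-like medians (−0.24) do not settle it either, since their clusters differ between organs. Of the 360 liver T, NK or ILC-like cells 358 lay in cluster 21, and those of the epidermis, gill and intestine mostly in cluster 12. T, NK or ILC-like cells of the heart, all in cluster 21, stood at −0.31, below those of the liver. Of the 95 liver DC-like cells, 75 lay in clusters 22 and 25, shared with the intestine, whose DC-like median was −0.45. Handling that acted on every liver cell therefore stays open. In the brain the B cell-like median was 0.43 over 52 cells, between the bounds set in advance, so handling and tissue cannot be told apart there with these few cells. The brain DC-like median was 0.80 over 728 cells but 0.16 under TMM scaling, so it stays open whether the rise in the brain reached beyond macrophage-like cells.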

How the results depend on the processing

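Chosen after seeing the data were the tests with doublets removed by score rank, with an ambient profile from other barcodes or without barcodes shared between libraries, the swaps of class labels and the reading of the split UMIs. The range of macrophage-like shares, 76.5 percentage points, became 82.8 with at least 500 UMIs and 250 genes, 74.0 with at least 2000, 80.4 with at most 5% and 74.4 with at most 20% mitochondrial UMIs. At 500 UMIs and 250 genes the brain was lowest at 0.951%, because its main cluster then stayed unnamed. The range of DC-like shares, 38.9 points, became 32.3 at 500 UMIs and 250 genes, 46.2 at 5% and 36.2 at 20% mitochondrial UMIs, and 36.9 with genes centred within libraries; the cause was not tested for these. Without the organ block 549 genes were higher in macrophage-like and 427 in DC-like cells, since the differences between organs then count as noise. Leaving out each organ in turn gave 843 to 1199 and 543 to 967 genes, with 543 without the intestine and 609 without the gill. DESeq2 called 1516 and 1200. Of 32 swaps of the class labels within organs, 1, the real one, gave 2103 genes and the next 37, but naming the classes from the same UMIs largely set this outcome. With classes from one random part of each cell's UMIs and the test on the other, 81.79% as many genes were called, 927 and 690 of them shared with the main lists, so reuse of the same UMIs does not explain them. The same swaps on those sums gave 1720 genes for the real labels and at most 18 otherwise, which excludes counting noise in the class names.

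Of 479 values of the named genes of this comparison, 476 stayed past the threshold. The exceptions came without the organ block: tppp and fabp7b (adjusted p 0.108) and timp4.3 (0.074). nrp2a was not tested without the gill. The microglia-associated, scavenger receptor, complement and lysosomal lists passed the preset test under all 19 alternatives, proliferation (without cycling cluster 3) under 8 and lipid handling under 2. Across organs, 600 of 666 gene values stayed within the counting interval of the main ratio. For lists, compared here in macrophage-like cells alone, 1145 of 1245 medians moved by at most 0.2 in log2. At 500 UMIs and 250 genes 34 list medians moved further and 40 did not, while at most 13 moved under any other setting. No gene ratio fell below a log2 of 0.83, and 1 value, vtg1, had nothing left after ambient subtraction. The lipid handling median of heart macrophage-like cells reversed, from −0.49 to 0.42, at 500 UMIs and 250 genes, where the brain dropped out of the comparison. Thinning to 1000 UMIs moved 77 of 100 shares of cells with a UMI. The depth limits genes near 3 counts per class, above all in the 95 liver DC-like cells.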

Other observations

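The tests of barcode chance and of intestinal carry-over were chosen after the values they use had been seen. The transgene and its gene of origin did not run in parallel across classes. The metaphocyte-like clusters 2, 10 and 11 stood at 3067, 2774 and 4448 CPM of DsRedx but at only 471, 572 and 560 CPM of mpeg1.1. DC-like cells stood at 2375 CPM of DsRedx and 4150 CPM of mpeg1.1 in the epidermis, and at 261 and 1794 CPM in the brain, where ambient levels were 226 and 616 CPM. Heart macrophage-like cells were lowest for both among macrophage-like cells, with DsRedx at 183 CPM and mpeg1.1 at 421 CPM. Ambient levels in the heart were 123.5 and 871 CPM, and no ambient share could be estimated there.

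Single genes of other lineages stood out in macrophage-like cells, and the values were chosen after they were seen. cd8a stood at 250 CPM in epidermal macrophage-like cells and was detected in 54.1% of them, or 20.6% after thinning to 1000 UMIs, against 2.03% of DC-like and 1.963% of metaphocyte-like cells of the same library at median depths of 8925, 7626 and 11560 UMIs. In cluster 0 its level was 171% of that in the T, NK or ILC-like cluster 12 and cd8b's was 38.1%. Cluster 12 holds 112 cells with 63 cd8a UMIs, and CD8 T cells were not told apart within it. Each other gene of the T, NK or ILC list with at least 30 UMIs in cluster 12 reached at most 2.001%, and the rest were not compared. rbp2a stood at 2726 CPM in intestinal macrophage-like cells against 999 CPM in ambient RNA of that library. Its level in clusters 6 and 18 was 1252% of that in the enterocyte-like cluster 29. Each other enterocyte gene of the list with at least 30 UMIs in cluster 29 reached at most 1.74%.

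Several clusters stayed unnamed although they carried hematopoietic genes. Cluster 5, with 604 cells from all 6 organs, had ctsbb at 1547 CPM, p2rx3a at 748 CPM, irf8 at 623 CPM, mpeg1.1 at 1481 CPM and flt3 at 236 CPM, and made up 7.12% of intestinal cells. Cluster 19, with 449 cells mostly from the intestine, had grn2 at 14260 CPM, grn1 at 5943 CPM, spi1b at 2105 CPM and ptprc at 1922 CPM. Cluster 3 held 508 cycling cells from all 6 organs with mki67 at 627 CPM. The T, NK or ILC-like cluster 21 of heart and liver had nkl.4 at 3347 CPM and flt3 at 794 CPM but lck at 12.8 CPM.

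The 75 liver cells of DC-like clusters 22 and 25 shared those clusters with 909 intestinal cells and may be a liver population or stray intestinal cells. Of these liver cells 0 carried a barcode called in the intestine library, which allows up to 4.80%, against 0.150% of the other 4672 liver cells. Macrophage-like cells of the intestinal clusters 6 and 18 were 26 per 75 such cells in the liver and 1719 per 909 in the intestine, a ratio of 0.18 (exact interval 0.11–0.29), which argues against carry-over of intestinal tissue as a whole. Enterocyte-like cells of cluster 29 were 9 per 75 in the liver and 124 per 909 in the intestine, or 0.12 and 0.136 per DC-like cell, as carry-over would give, so carry-over of part of the cells stays open. ifit8 was detected in 58.7% of the liver cells and in 0 of the 909 intestinal ones, and isg15 in 70.7% and 2.2%. A liver population in an interferon-exposed state remains a hypothesis, and an interferon response of the pooled fish or of the liver library alone stays open.

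The libraries fall into 3 pairs by shared barcodes. In each library between 10.3% and 34.6% of the barcodes with 10 to 99 UMIs were cells of its partner, against at most 0.224% for any other pair of libraries, which excludes chance sharing of barcodes. Across these partner barcodes, UMIs in the library followed UMIs in the partner with rank correlations between 0.87 and 0.95, and between −0.03 and 0.04 in other pairs. These values are consistent with reads assigned to the wrong library of a pair, at 0.303% to 1.26% of the partner's UMIs. The low-UMI barcodes of a library, and so its ambient profile, then hold RNA of the partner organ, 41.3% of these UMIs in the gill and 5.20% in the epidermis.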
